A study of Mus musculus with 6 samples.

How the data were processed

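RNA of mouse (BALB/c) bone marrow monocytes was measured on 6 Affymetrix arrays, 3 from cultures with dexamethasone and 3 from control cultures. Per the labels' protocols, bone marrow cells were enriched for monocytes on a density gradient, depleted magnetically of cells carrying CD11c, CD19 or CD90, and kept for 16 h in medium with the growth factor M-CSF (50 ng/ml), to which either the synthetic glucocorticoid dexamethasone (40 ng/ml) or its solvent was added. Biotinylated cRNA was made from total RNA and hybridised. The deposited values are intensity values on a linear scale, 1 per probe set and array. The only software named in the submitters' processing notes is GCOS, the array maker's operating software; its version, its settings and any background step are not given in the sources used here. In all 6 columns the mean after trimming 2 percent from each end is 100, as the values themselves show, so the arrays had been scaled before deposit. The table has no detection call per probe set, so no probe set was called present or absent.

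The table holds 45101 probe sets, of which 64 are control probe sets and 34958 carry 1 gene symbol in the platform annotation (18194 different symbols). A further 932 carry several symbols and 9160 are not named here; none of these was used in the tests of genes. Symbols of 34754 probe sets were matched to RefSeq (mouse assembly GRCm38.p6) through their gene numbers, and none changed. No reference genome was used, and no positions are given.

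Because the trimmed means were equal, no further normalization was applied. Signals were transformed as log2(signal + 4.1), where 4.1 is the median over the arrays of their 25th percentile; differences on this scale understate the change of genes with low signal. Control probe sets and the 40 percent of probe sets with the lowest mean were left out, and each gene was represented by its probe set with the highest mean over all 6 arrays, which left 12557 genes. Dexamethasone was compared with control by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. This fit had no block. The design, the rule on normalization, the gene lists, the rule for naming genes and all alternatives except those named at the end were set before the data were examined.

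The titles number the arrays of each group from 1 to 3, and the series' design text speaks of independent experiments. Arrays with the same number deviated together from their group means, with correlations of 0.29, 0.45 and 0.48 for the 3 pairs. The highest correlation between a control and a dexamethasone array of different numbers was -0.04. Deviations cancel out within a group, so positive correlations of same-numbered arrays push the others down, and the latter are no separate evidence. Because of their positive correlations, same-numbered arrays were treated as coming from 1 experiment. A fit with the number as a block, called the paired fit below, is given beside each result whose call or count it changes. Whether the experiments used different animals is not given in the sources used here. The number of arrays, 3 per group, limits the precision of every value.

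Lists of genes were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 19 gene lists and, separately, over the 12 cell marker lists, and again with an estimated correlation and with fry. The lists hold 526 different genes, of which 485 are named on the array and 437 were tested. With an estimated correlation, 0 of the 19 gene lists and 0 of the 12 cell marker lists were called by camera, against 3 and 1 with an unadjusted p under 0.05; fry called 3 gene lists and 0 cell marker lists. Genes are named below by rule: the 12 largest rises and up to 12 largest falls among called genes whose groups did not overlap (10 falls qualified), 2 to 4 members of each list by lowest adjusted p in each direction, any further list member given with its value, Nr3c1, and 3 glucocorticoid targets as a check of the labels. The rule had not stated which fit ranks the list members. They were taken from those called in the paired fit, in the order of its adjusted p. The further members, among them Sgk1, Il10, Adgre1, Ptgs2 and Ccl5, were picked from the lists after their values were seen. Predicted and unnamed genes were left out of the largest changes, and other genes are said to have been chosen after their values were seen.

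The calculations were tested on simulated data for the dexamethasone comparison, with the means of the 12557 genes, 200 changed genes and 10 runs per condition. Without the block, 0 percent of genes changed 2-fold were recovered, and 67.4 or 66.1 percent of those changed 4-fold. With the block, 72.0 or 53.9 percent of genes changed 2-fold and 89.8 or 85.3 percent of those changed 4-fold were recovered. The first value of each pair used each gene's own moderated spread and the second a spread drawn from the fitted prior. Of the calls with the block, 7.57 and 5.19 percent at 2-fold, and 5.87 and 5.27 percent at 4-fold, were of unchanged genes, slightly above the nominal share. A first run of this test, with 1 draw and each gene's own spread, had exceeded its preset limit on such calls; the second way of drawing spreads and the averaging over 10 runs were added after that. Alternatives tried were other pseudocounts, filters, normalizations, ways of choosing probe sets and variance models, a stricter threshold, the block, the other list tests, and leaving out each array; leaving out both arrays of an experiment and quantile normalization with the block were added after the data were examined.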

Results

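The data comprise 6 arrays of bone marrow cells enriched for monocytes and cultured for 16 h with M-CSF. Of the arrays, 3 are from cultures with dexamethasone and 3 from cultures with solvent. The comparison asks which genes differed with dexamethasone in these cultures. Other cells could be present, and the arrays do not give the cells that a change came from. Values below are log2(signal + 4.1), as mean ± SD with n = 3 arrays per group, and differences are dexamethasone minus control. The median signal per array lay between 14.2 and 20 on the scale whose trimmed mean is 100. It was highest on the dexamethasone array of experiment 3, whose 25th percentile was 7, against 3.6 to 4.4 on the others. The 2 arrays of experiment 3 stood apart, with signals of 4825 (control) and 3649 (dexamethasone) at the 3′ control probe set for 18S ribosomal RNA, against 94.6 to 235 on the other 4 arrays. The 3′ to 5′ signal ratio of beta-actin, a measure of RNA integrity, was highest on the dexamethasone array of experiment 3 (2.54, against 1.29 to 1.83 on the others). The first principal component (36.4% of the variance) separated the arrays of experiment 3 from the others, and the second (25.9%) separated dexamethasone from control.

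**Figure D1:**
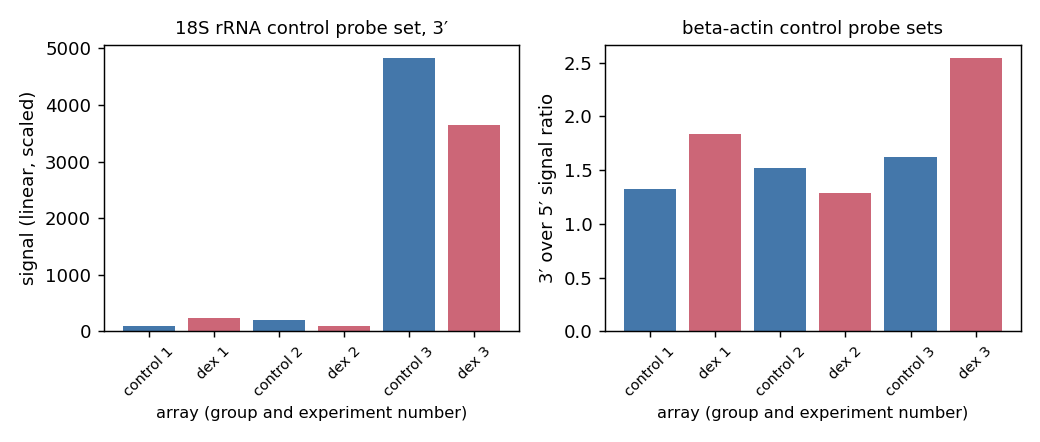
Signal of the 3′ 18S rRNA control probe set (left, linear scaled signal) and the 3′ to 5′ signal ratio of the beta-actin control probe sets (right) on each of the 6 arrays, control in blue and dexamethasone (dex) in red. The experiment 3 arrays had 18S signals of 4825 and 3649, and dexamethasone array 3 had the highest actin ratio, 2.54.

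The known glucocorticoid receptor targets Fkbp5, Tsc22d3 and Per1 had higher values on each dexamethasone array than on any control array. Fkbp5, a co-chaperone of the receptor, was 7.99, 8.53 and 7.95 on control arrays 1, 2 and 3 and 11.14, 10.88 and 10.45 on the dexamethasone arrays (adjusted p = 0.00527). Tsc22d3, which encodes the anti-inflammatory protein GILZ, was 7.51, 7.12 and 7.39 on the control arrays and 9.88, 9.40 and 9.04 on the dexamethasone arrays (adjusted p = 0.0103). The clock gene Per1 was 6.55, 5.07 and 6.24 on the control arrays and 7.34, 6.94 and 7.33 on the dexamethasone arrays, a difference called in the paired fit (adjusted p = 0.00384) and not without the block (0.370). One label field of control array 1 mentions dexamethasone while its title, description and treatment do not; its values for these 3 genes lay below every dexamethasone array. Nr3c1, the glucocorticoid receptor itself, was at 8.50 ± 0.39 in control and 8.44 ± 0.21 in dexamethasone cultures and was not called (adjusted p = 0.987).

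Dexamethasone raised 40 genes and lowered 10 of the 12557 tested, all by at least 2-fold. In the simulated data this fit recovered 0 percent of genes changed 2-fold. The size of the 50 called changes therefore reflects in part what the fit can call. Among these 50 the largest rise was that of Bcl2l15, a gene of the Bcl-2 family, from 2.73 ± 0.71 to 9.02 ± 1.54 (difference 6.29, SE 0.69, adjusted p = 0.00714); its control signal was close to the pseudocount, and the difference lay between 4.88 and 7.28 over the alternatives. Prnp, the prion protein gene, rose by 3.80 (SE 0.40), from 7.55 ± 0.85 to 11.36 ± 0.45. Rises of about 3 or more were also found for Ms4a8a (4.07, SE 0.40), the carboxylesterase gene Ces2g (3.96, SE 0.50), Adamtsl4 (3.87, SE 0.27), the orphan receptor gene Gprc5b (3.64, SE 0.43) and the transcription factor gene Zbtb16 (3.35, SE 0.49). Il1r2, the decoy receptor for interleukin-1, rose by 3.11 (SE 0.33), the transcription factor gene Klf9 by 2.99 (SE 0.28), and Rnase2a, Gpc3 and Ecm1 by 2.98, 2.98 and 2.86. The control levels of Gpc3 (2.42) and Gprc5b (2.65) were as close to the pseudocount as that of Bcl2l15, and over the alternatives their differences lay between 1.71 and 4.02 and between 2.37 and 4.50.

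Among the genes called without the block, the largest fall was that of H2-Ea, an MHC class II alpha chain gene, from 9.75 ± 0.26 to 7.41 ± 0.69 (difference -2.34, SE 0.33, adjusted p = 0.0231). B cell and dendritic cell markers had medians of -1.40 and -1.46, and both cell types express MHC class II genes. Which cells the fall of H2-Ea came from was not tested. The integrin gene Itga8 fell by 1.98 (SE 0.27), the beta-glucan receptor gene Clec7a by 1.79 (SE 0.28) and Olfm1 by 1.79 (SE 0.19). The interferon-induced genes Rsad2, Ifit2 and Ifit1 fell by 1.90, 1.61 and 1.58. The transcription factor gene Mef2c differed by -1.51, Bex6 by -1.68 and Igfbp4 by -1.47, and these 3 also passed the test. The 10 of these 22 genes that had another tested probe set had 24 such probe sets, all with the same sign, of which 8 were called on their own.

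The paired fit called 700 genes (371 higher, 329 lower), 318 of them changed at least 2-fold (175 higher, 143 lower), and included all 50 genes called without the block. The groups did not overlap for 1584 genes (12.6%), where chance gives 10% if the 6 arrays are interchangeable. Arrays of the same number deviated together, so 10% is not the chance share of these arrays, and the excess was not tested. The count of 50 fell to 12 without control array 1, to 8 without dexamethasone array 1, to 25 without control array 2 and to 31 without control array 3; it was 52 without dexamethasone array 2 and 63 without dexamethasone array 3, each including 42 of the 50. All 50 genes kept their sign in each of these 6 fits. This was fixed in advance, because the groups did not overlap for any of the 50. Without both arrays of experiment 1, limma called 0 genes (424 at an unadjusted p under 0.05), or 328 with the block. Without both arrays of experiment 2 it called 15, or 1236 with the block, and without both arrays of experiment 3 it called 76, or 884 with the block.

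**Figure D2:**
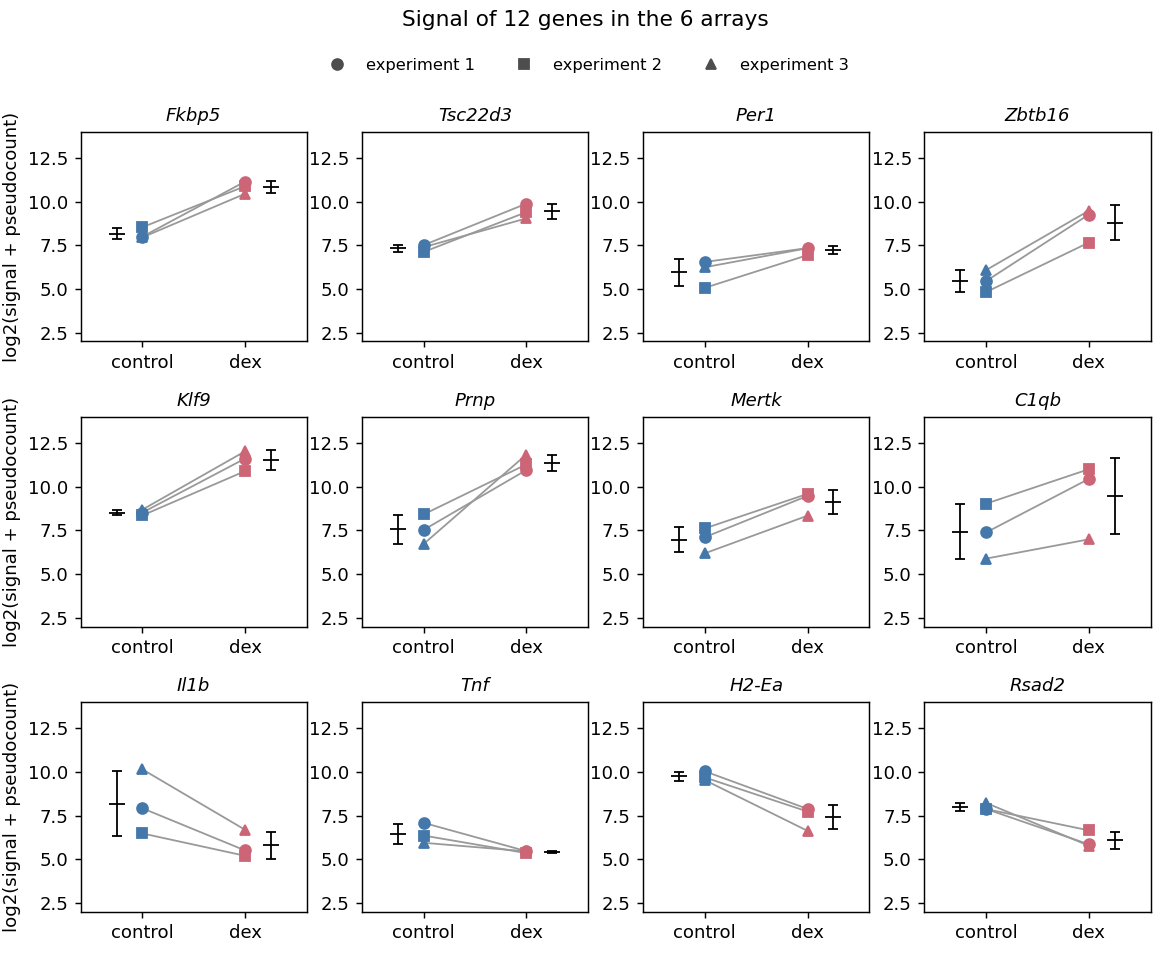
Level of 12 genes, as log2(signal + 4.1), on the control (blue) and dexamethasone (dex, red) arrays, with lines joining the arrays of 1 experiment and black bars giving the mean ± SD of 3 arrays. Fkbp5 lay between 7.95 and 8.53 on the control arrays and between 10.45 and 11.14 on the dexamethasone arrays, and C1qb differed more between experiments than between treatments.

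Glucocorticoid receptor targets rose as a group, with a median difference of 1.33 over 24 tested genes (camera adjusted p = 8.01e-17). The adjusted p was 0.0998 with an estimated correlation, and the median 0.69 without probe sets that can detect several transcripts. Over all genes tested 6 members rose, and 0 fell: Fkbp5, Klf9, Il1r2, Tsc22d3, Zbtb16 and Pik3ip1 (2.50, SE 0.30), a negative regulator of PI3-kinase. Adjusted over the list alone, 13 rose and 1 fell. The paired fit called 14 higher, among them Ddit4 (2.48), the macrophage scavenger receptor gene Cd163 (2.47), the MAP kinase phosphatase gene Dusp1 (2.30) and the glutamine synthetase gene Glul (1.66), and 2 lower, Hsd11b1 (-0.83), whose enzyme regenerates active glucocorticoids, and Rgs2 (-0.66). Sgk1 differed by 0.48 and was not called.

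Interferon-stimulated genes fell as a group, with a median of -0.61 over 31 tested genes and 30 of the 31 below 0 (camera adjusted p = 4.03e-18; adjusted p = 0.0526 with an estimated correlation). Over all genes 3 fell, Rsad2, Ifit2 and Ifit1, and 14 fell when adjusted over the list alone; the paired fit called 13 lower and 0 higher. Those included Ifit3 (-2.43), the deconjugating protease gene Usp18 (-1.83), the antiviral GTPase gene Mx1 (-1.69), Oasl2 (-1.39) and the transcription factor gene Irf7 (-1.14). Ifit3 differed by -4.06, -1.68 and -1.55 in experiments 1, 2 and 3, and its level on dexamethasone array 1 (2.46) was close to the pseudocount. The median of the list was -0.56, -0.55 and -0.72 in experiments 1, 2 and 3. On the same arrays the markers of B cells and of dendritic cells had medians of -1.40 and -1.46.

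Genes of antigen presentation and costimulation fell with a median of -0.78 over 14 tested genes (camera adjusted p = 1.86e-06; adjusted p = 0.0998 with an estimated correlation). None was called over all genes tested by limma, 8 fell adjusted over the list alone, and the paired fit called 7 lower and 0 higher. The MHC class II genes H2-Eb1 (-2.16, SE 0.20 in the paired fit), H2-Aa (-1.80, SE 0.17) and H2-Ab1 (-1.45, SE 0.17) and the invariant chain gene Cd74 (-1.99, SE 0.24) fell in it, as did H2-Ob (-2.20) and the costimulatory receptor gene Cd40 (-1.44). On the same arrays the markers of B cells and of dendritic cells, which also present antigen, had medians of -1.40 and -1.46. With every probe set tested on its own, the median of the antigen presentation list was -1.18.

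Pro-inflammatory mediators had a median of -0.35 over 9 tested genes and passed camera in the paired fit (adjusted p = 0.0191; adjusted p = 0.299 with an estimated correlation) and not without the block (0.109). Without control array 2, but with no block, the median was -0.64 (adjusted p = 0.00187), and without both arrays of experiment 2 it was -0.70 (0.0178), so that the list was called. Of these genes 0 were called over all genes without the block, 1 rose and 2 fell adjusted over the list alone, and the paired fit called the cytokine genes Il1b (-2.39, SE 0.30) and Tnf (-1.04, SE 0.24) lower and Il18 (0.69, SE 0.16) higher. Ptgs2, the inducible cyclooxygenase gene, differed by -1.05 and was not called. Chemokines fell with a median of -0.53 over 16 tested genes (camera adjusted p = 0.0218; adjusted p = 0.429 with an estimated correlation). No chemokine was called without the block, over all genes or adjusted over the list alone; in the paired fit Cxcl10 (-1.37) and Cxcl14 (-1.33) fell, while Ccl5 differed by -1.57 and was not called. The chemokine median was -0.27, -0.12 and -0.99 in experiments 1, 2 and 3, and the group's call was lost without control array 1, dexamethasone array 2, control array 3 or dexamethasone array 3 (medians -0.28, -0.30, -0.35 and -0.43, adjusted p = 0.155, 0.0963, 0.147 and 0.140). It was also lost with the lowest 60 percent left out (adjusted p = 0.275) and without both arrays of experiment 3 (median -0.22, adjusted p = 0.285, or 0.246 with the block).

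Genes of alternative activation rose with a median of 0.31 over 22 tested genes (camera adjusted p = 0.0258; adjusted p = 0.507 with an estimated correlation), and members went both ways. Over all genes the chitinase-like gene Chil3 (1.26, SE 0.17) and the coagulation factor gene F13a1 (1.06, SE 0.17) rose; adjusted over the list alone 5 rose and 1 fell. The paired fit called 8 higher, including Cd163, the fibronectin gene Fn1 (2.25), the lectin gene Clec10a (1.05) and the arginase gene Arg1, and 3 lower, Igf1 (-1.95), Cd36 (-1.94) and Il1rn (-1.62). Arg1 differed by 2.78, 3.56 and 0.12 in experiments 1, 2 and 3, and Il10 differed by 0.38 and was not called. The group's call was lost without dexamethasone array 1, dexamethasone array 2 or control array 3 (medians 0.20, 0.23 and 0.12, adjusted p = 0.207, 0.0963 and 0.177). It was also lost with every probe set (0.176), with no intensity trend (0.0813) and without both arrays of experiment 1 or 2 (0.0774 and 0.0812), and the median was 0.58 without control array 1 and 0.60 without dexamethasone array 3. On the same arrays the markers of maturing macrophages also had a median of 0.31.

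Phagocytosis and efferocytosis receptors, which take up particles and dying cells, passed camera in the paired fit (adjusted p = 0.0376; adjusted p = 0.515 with an estimated correlation) and not without the block (0.317), with a median of 0.17 over 24 tested genes. With no block the list was called without control array 2 (median 0.28, adjusted p = 0.0185), dexamethasone array 3 (0.35 and 0.000480) or both arrays of experiment 3 (0.0895 and 0.00378), while its median was -0.0223 without control array 3 and 0.0679 without dexamethasone array 2. With the block its call was lost without both arrays of experiment 1 or 2 (adjusted p = 0.117 and 0.0742). Only Clec7a was called over all genes without the block, and 1 rose and 1 fell adjusted over the list alone. Maturing macrophage markers, 4 of which belong to both lists, had a median of 0.31. Of the phagocytosis and efferocytosis list, 6 genes rose in the paired fit, among them the efferocytosis receptor gene Mertk (2.17, SE 0.15) and the complement genes C1qb (2.05), C1qa (1.80) and C1qc (1.70). In the same list 4 fell, among them Cd36, Axl (-1.12) and the ligand gene Gas6 (-0.76). Migration and adhesion genes had a median of -0.06 over 22 tested genes and passed camera in the paired fit (adjusted p = 0.0261; adjusted p = 0.515 with an estimated correlation), not without the block (0.0952). With no block this list was called without control array 2 (median -0.18, adjusted p = 0.0119), without both arrays of experiment 2 (-0.19 and 0.00110), with every probe set (-0.19 and 0.00334) and with no filter (-0.0757 and 0.0285), and its median was -0.0179 without control array 3. With the block its call was lost without both arrays of experiment 3 (adjusted p = 0.203). Of these, 0 were called over all genes without the block and 3 fell adjusted over the list alone. The paired fit called the integrin gene Itgax (-1.58), Cx3cr1 (-1.59), Vcam1 (-1.44), the monocyte chemokine receptor gene Ccr2 (-1.12) and Icam1 (-0.94) lower and the formyl peptide receptor gene Fpr2 (0.54) higher.

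Cell cycle genes fell with a median of -0.31 over 29 tested genes (camera adjusted p = 6.67e-07; adjusted p = 0.474 with an estimated correlation). None was called over all genes by limma without the block, 1 fell adjusted over the list alone, and the paired fit called 5 lower, including the cyclin gene Ccnd1 (-1.85), the thymidine kinase gene Tk1 (-1.08) and the replication licensing genes Mcm2 (-0.68) and Mcm3 (-0.62). The median was -0.16 without dexamethasone array 3. On the same arrays the markers of granulocyte-monocyte progenitors had a median of -0.39, with Kit (-0.82) and Cd34 (-0.67) lower in the paired fit. Cholesterol synthesis genes fell with a median of -0.29 over 17 tested genes (camera adjusted p = 0.00777; adjusted p = 0.507 with an estimated correlation), with 0 members called by limma over all genes, with or without the block. Adjusted over the list alone without it, 0 were called. The median of the cholesterol synthesis list was -0.47, -0.0248 and -0.44 in experiments 1, 2 and 3. Fdps (-0.58) and Cyp51 (-0.49) had the most negative values, and the call was lost without control array 1 or dexamethasone array 3 (medians -0.18 and -0.15, adjusted p = 0.221 and 0.226) and without both arrays of experiment 1 (0.0774, or 0.0574 with the block).

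The other 9 gene lists were not called by camera, with or without the block. In the paired fit 5 of 19 lipid handling genes rose, including the apolipoprotein genes Apoe (1.14) and Apoc2 (1.44) and the lipase gene Pnpla2 (1.15), and 4 fell, including Lpl (-1.21) and Lipa (-0.95). Adjusted over the list alone without the block, 2 rose and 2 fell (camera adjusted p = 0.783). Of 17 proteases and matrix genes, Mmp19 rose over all genes (1.86, SE 0.29), 2 rose and 1 fell adjusted over the list alone. The paired fit added Mmp8 (1.35) among 4 higher and Mmp12 (-2.58), Plau (-2.05) and Mmp13 (-1.12) among 4 lower (0.783). Of 23 pattern recognition genes, Clec7a fell over all genes and adjusted over the list alone, while the paired fit called Tlr7 (1.28), Tlr6 (0.66) and Tlr13 (0.61) higher and Cd14 (-0.74) and Clec4n (-0.70) lower beside it (0.783). Of 17 genes of the NF-kB pathway, the inhibitor gene Nfkbia (1.41) and Birc3 (1.42) rose and Nfkbie (-0.76) fell in the paired fit, and 2 rose adjusted over the list alone (0.833). Of 22 immediate early genes and MAP kinase feedback genes, Dusp1 and Fos (0.62) rose and Egr3 (-1.41), Egr2 (-1.36) and Dusp4 (-1.17) fell in the paired fit, and 0 were called adjusted over the list alone (0.177). Of 14 clock genes, Per1 and Nfil3 (0.85) rose and Nr1d2 (-1.09) fell in the paired fit, and 1 fell adjusted over the list alone (0.853). Of 17 antioxidant and metal defence genes, Gpx3 (2.20), the heme oxygenase gene Hmox1 (0.75) and the metallothionein gene Mt1 (0.67) rose in the paired fit, and 1 rose adjusted over the list alone (0.383). Of 20 effectors of myeloid suppressor cells, Arg1 and Cebpb (0.70) rose and the oxidase gene Cybb (-0.51) fell in the paired fit, and 0 were called adjusted over the list alone (0.312). None of 16 apoptosis regulators was called in either fit, nor adjusted over the list alone without the block (0.937). Camera's direction was up, and the median below 0, for apoptosis regulators (-0.01), pattern recognition (-0.03) and clock genes, while proteases had a median of 0.10, a mean of -0.11 and the direction up (down with quantile normalization).

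**Figure D3:**
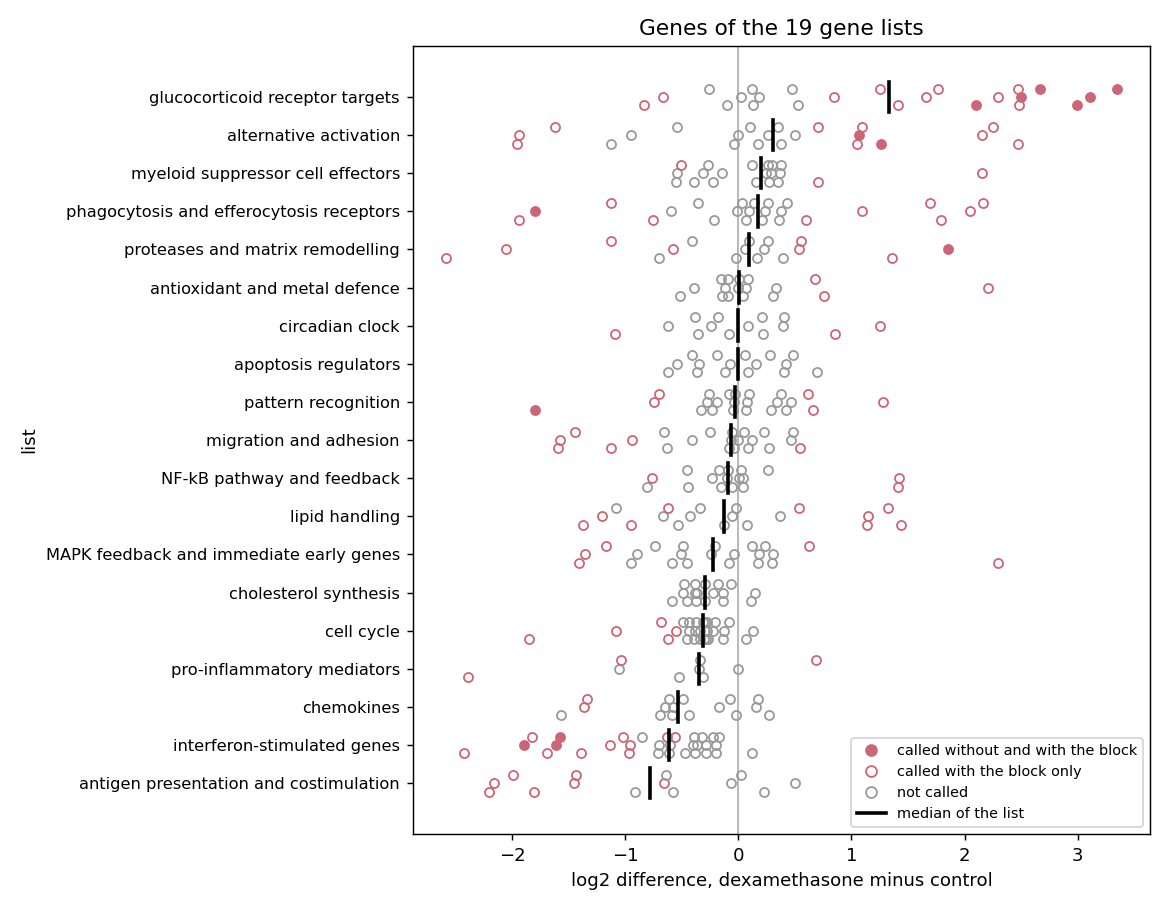
Difference (log2, dexamethasone minus control) of each tested gene, by gene list, with filled red points for genes called without and with the block, open red points for genes called with the block only, grey points for genes not called, and black lines for list medians. List medians ran from -0.78 for antigen presentation to 1.33 for glucocorticoid receptor targets.

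Markers of cell types that the cultures could hold differed between the groups as well. B cell markers fell with a median of -1.40 over 10 tested genes (camera adjusted p = 7.69e-05; adjusted p = 0.581 with an estimated correlation), although CD19-bearing cells had been depleted. In the paired fit the B cell receptor genes Cd79a (-2.06), Cd79b (-1.69) and Ighm (-1.75) and the adaptor gene Blnk (-1.94) fell; 0 were called over all genes without the block and 1 fell adjusted over the list alone. Their median was -1.03, -0.33 and -3.14 in experiments 1, 2 and 3, and the call was lost without control array 3 (median -0.73, adjusted p = 0.105), which had the highest Cd79a (8.78, against 5.33 and 4.03 on control arrays 1 and 2). Without control array 2 the median was -2.12. Dendritic cell markers fell with a median of -1.46 over 10 tested genes (camera adjusted p = 0.00984; adjusted p = 0.581 with an estimated correlation), among them, in the paired fit, 6 lower and 1 higher. The lower ones included the chemokine receptor gene Ccr9 (-3.22), Cd209a (-1.74), Itgax, Irf4 (-1.51) and Siglech (-1.48), and the higher one was the cytokine receptor gene Flt3 (1.74, SE 0.20). Without the block 0 were called over all genes, 1 rose and 5 fell adjusted over the list alone, and the group's call was lost without dexamethasone array 2 or control array 3 (medians -0.92 and -0.87, adjusted p = 0.116 and 0.132) and without probe sets that can detect several transcripts (median -1.08, adjusted p = 0.133).

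Maturing macrophage markers rose with a median of 0.31 over 11 tested genes (camera adjusted p = 0.0364; adjusted p = 0.697 with an estimated correlation). In the paired fit Mertk, C1qa, C1qb, C1qc and Apoe rose, 0 fell, and the other 6 were not called, among them Adgre1 (-0.34), which encodes the antigen F4/80; without the block 0 were called over all genes and 1 rose adjusted over the list alone. The call was lost without dexamethasone array 1, dexamethasone array 2 or control array 3 (medians 0.0593, 0.18 and 0.0227, adjusted p = 0.312, 0.544 and 0.569) and with quantile normalization (median 0.15, adjusted p = 0.0586). It was also lost with no filter (0.0543), with no intensity trend (0.0686) and without both arrays of experiment 1 (0.291). Without control array 1 or dexamethasone array 3 the median was 0.98 or 1.27. Markers of granulocyte-monocyte progenitors fell with a median of -0.39 over 10 genes (camera adjusted p = 0.0171; adjusted p = 0.581 with an estimated correlation), with Nkg7 (-0.97), Kit (-0.82) and Cd34 (-0.67) lower in the paired fit. Without the block 0 were called over all genes or adjusted over the list alone, and the group's call was lost without dexamethasone array 2 or control array 3 (medians -0.0833 and -0.0869, adjusted p = 0.443 and 0.370). Without control array 2 the median was -0.60. Eosinophil markers fell with a median of -0.96 over 4 tested genes (camera adjusted p = 0.00993; adjusted p = 0.447 with an estimated correlation), with the granule protein genes Prg2 (-1.33) and Epx (-1.30) lower in the paired fit. Without the block 0 were called over all genes or adjusted over the list alone, and the group's call was lost without dexamethasone array 2 or control array 3 (medians -0.70 and -0.76, adjusted p = 0.116 and 0.105).

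The other 7 marker lists were not called by camera. Of 8 monocyte markers, F13a1 rose over all genes, 2 rose and 1 fell adjusted over the list alone, and the paired fit added Ms4a6c (1.18) higher and Ccr2, Cx3cr1 and Cd14 lower (camera adjusted p = 0.952). Of 12 neutrophil markers, Mmp8 and Lcn2 (0.48) rose and the lactoferrin gene Ltf (-0.68) fell in the paired fit, and 1 rose adjusted over the list alone (0.952). In control cultures Mmp8 was at 11.64 ± 0.47, Lcn2 at 12.70 ± 0.14 and Ltf at 12.62 ± 0.13, values that do not give the cells' shares. Whether changes of such genes came from monocytes or from neutrophils was not tested. In the paired fit 1 gene fell in each of the erythroid (Tfrc, -0.99), megakaryocyte and platelet (Ppbp, -0.69), basophil and mast cell (Mcpt8, -0.82) and T and NK cell lists (Cd3d, -0.65). Their camera adjusted p were 0.178, 0.909, 0.677 and 0.290, in this order. Adjusted over the list alone without the block, only an erythroid gene, 1 of 7, fell. Only 2 T and NK cell genes were tested, and the 7 stromal and endothelial genes held 0 called genes in either fit and 0 adjusted over the list alone (0.356). The megakaryocyte list had a median of -0.00361 and a mean of -0.02 with camera's direction up.

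**Figure D4:**
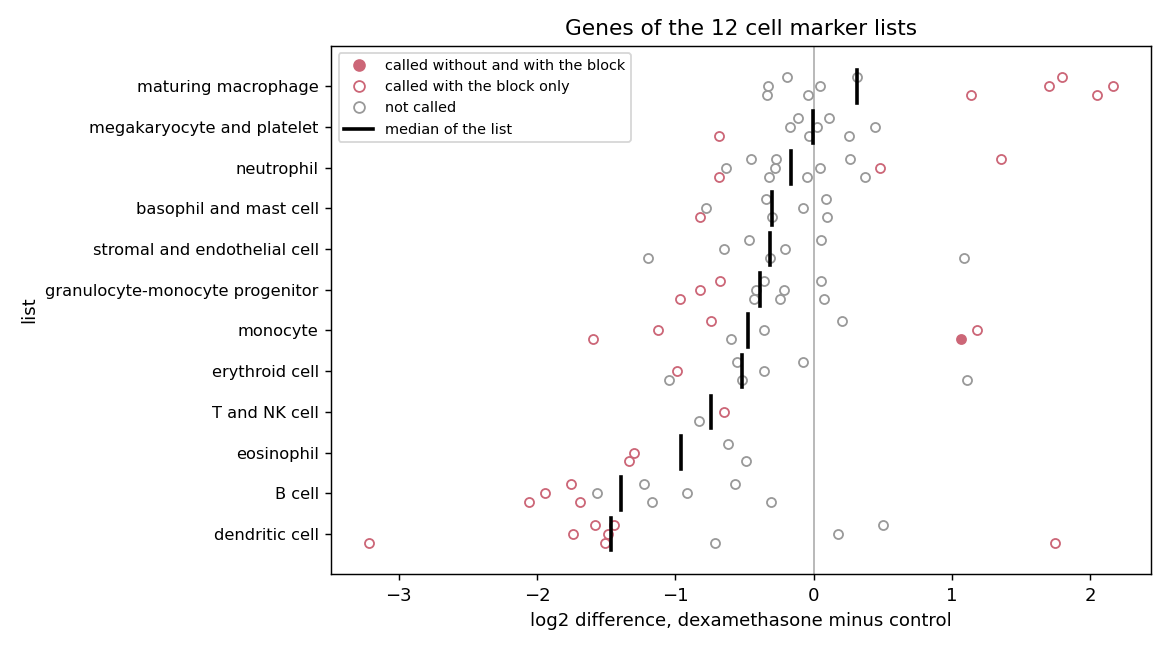
Difference (log2, dexamethasone minus control) of each tested gene, by cell marker list, with filled red points for genes called without and with the block, open red points for genes called with the block only, grey points for genes not called, and black lines for list medians. Dendritic cell and B cell markers had the lowest medians, -1.46 and -1.40.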

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

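The tests of array quality, of genes matched on level and of cell sources, and the counts over other splits of the arrays, were chosen after the results had been seen. In the fit of every probe set, 82 of 27022 were called, and 9 probe sets without a single gene name were higher with dexamethasone and 2 lower; they lie outside the tests of genes, and their genes are not named here. Groups of 3 arrays are too small for the test of single outlying arrays.

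The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 50 genes, all at least 2-fold, and the highest other split 1; only 1 of the 10 splits, the real one, gave as many. For the gene lists the real split called 7 and the highest other split 9, with 4 splits giving as many; for the cell marker lists the values were 5 and 9, also with 4 splits. For either kind of list, the other 3 splits that called as many kept the 2 arrays of some experiment together. The cause of their counts was not tested. These list counts used camera at the preset correlation of 0.01. With an estimated correlation the real split called 0 lists of either kind. Among the 4 splits that part all 3 pairs, the highest other counts were 0 genes, 6 gene lists and 2 cell marker lists. In the paired fit the real split called 700 genes, 318 of them at least 2-fold, 10 gene lists and 5 cell marker lists, and the highest other of those splits 0, 0, 6 and 1.

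Interferon-stimulated genes were lower with dexamethasone by a median of -0.61. On the arrays of experiment 3 as the cause, the medians in experiments 1 and 2 were -0.56 (SE 0.15, from resampling genes) and -0.55 (SE 0.18). The list was thus also lower outside experiment 3. Both medians lay more than 2 SE below 0, but this SE treats genes as independent and holds no spread between arrays. With 1 array per group in each experiment, it cannot test the difference of a single experiment. A stricter bound tried first (beyond -0.36, a fraction of the value in experiment 3, by 2 SE) had left this cause undecided, here and for antigen presentation, but it asked for more than the explanation forbids. Against an intensity-dependent difference between arrays, 10000 lists of genes matched on level had a median of -0.0466 and a lowest of -0.33. A smaller share of B cells or dendritic cells as the source stays open: the list minus the B cell markers was -0.22 (SE 0.34) in experiment 2, the lowest of the experiments, and the list minus the dendritic cell markers was at lowest 0.38 (SE 0.61). A response of the monocytes to dexamethasone, which the design names, is among the open explanations.

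Genes of antigen presentation were lower by a median of -0.78. The list was also lower outside experiment 3, with medians of -0.73 (SE 0.26) in experiment 1 and -0.97 (SE 0.38) in experiment 2. Each lay more than 2 SE below 0, but the SE, again from resampling genes, holds no spread between arrays. Loss of B cells or dendritic cells, both of which express MHC class II genes, cannot be told apart from a response of the monocytes: in experiment 2 the list minus the B cell markers was -0.64 (SE 0.48) and the list minus the dendritic cell markers -0.0362 (SE 0.70), both within 2 SE of 0. Cells carrying CD19 or CD11c had been depleted before culture. In control cultures the B cell gene Ighm was at 10.95 ± 1.10 and the dendritic cell gene Ccr9 at 8.14 ± 2.28 (n = 3), values that do not give the cells' shares.

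C1qa, C1qb, C1qc, Mertk and Apoe were higher by a median of 1.80. These 5 were picked as the markers called in the paired fit, so their medians of 2.62 (SE 0.29) in experiment 1 and 1.89 (SE 0.33) in experiment 2 decide nothing on the arrays of experiment 3 as the cause; over all 11 markers the medians were 0.41, 0.41 and 0.12 in experiments 1, 2 and 3. The other 6 tested markers had a median of -0.11. They are what the pick left, so a lower median than that of the 5 was favoured by it and decides nothing. Levels of different probe sets cannot be compared either, so that a high baseline of these 6 could hide a small share. A higher share of maturing macrophages therefore stays open. A response of the monocytes to dexamethasone is likewise open.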

How the results depend on the processing

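Leaving out both arrays of an experiment, with and without the block, and quantile normalization with the block were chosen after seeing the data. The count of 50 genes, all at least 2-fold, lay between 42 and 62 under 9 alternatives: other pseudocounts (50 and 49), no filter (43), the lowest 60 percent left out (47), quantile normalization (51), median centring (62), the mean over probe sets (52), leaving out probe sets that can detect several transcripts (42) and a robust trend (54). It was 82 with every probe set tested on its own, 30 without the intensity trend and 16 at an adjusted p under 0.01, in each case all at least 2-fold. With the replicate block it was 700 (318 at least 2-fold), and 643 (302) with quantile normalization and the block. Leaving out arrays gave 0 to 1236 genes (0 to 452 at least 2-fold). The count was 0 without both arrays of experiment 1 in limma without the block (424 at an unadjusted p under 0.05). It was 1236 without both arrays of experiment 2 with the block. Fits with fewer arrays gave both lower and higher numbers than the fits of all arrays, and the cause was not tested. The 22 genes named for the largest changes kept their sign in every alternative, and all 22 were called with the block without any 1 experiment. On leaving out arrays the sign could not turn, because the groups of these 22 genes did not overlap. Without the block fewer of the 22 stayed called: 5, 12 and 13 without control array 1, 2 or 3, 4, 18 and 18 without dexamethasone array 1, 2 or 3, and 0, 9 and 19 without both arrays of experiment 1, 2 or 3. Mef2c was not called in 13 of 26 alternatives, Ifit1, Ifit2 and Rsad2 in 10 of 26, Gpc3 in 10 of 25, and the other 17 in 1 to 9. No normalization moved the share of rises by more than 10 percentage points (80.0 percent, against 80.4 with quantile normalization and 79.0 with median centring), and the median over all genes was -0.02, or -0.10 with median centring. Other choices moved this share further, to 53 percent with the block and to 90 percent without the intensity trend.

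Of the 19 gene lists 7 were called, against 0 with an estimated correlation, 3 by fry, 10 with the block and 5 to 11 on leaving out arrays; of the 12 cell marker lists 5, against 0 with an estimated correlation, 0 by fry, 3 at an adjusted p under 0.01, 5 with the block and 0 to 9 on leaving out arrays. With a single choice changed at a time, and for the alternatives with the block that used camera at the preset correlation, the lowest and highest adjusted p were 2.14e-60 and 0.0998 for glucocorticoid receptor targets, 2.56e-19 and 0.0526 for interferon-stimulated genes and 2.48e-13 and 0.0998 for antigen presentation, the highest with an estimated correlation, which ended these 3 calls. With an estimated correlation and the block together they were 0.133, 0.133 and 0.275. Fry with the block called 3 gene lists and 0 cell marker lists; with it antigen presentation was not called (adjusted p = 0.0916, against 0.0362 without the block) and the cell cycle was (0.00199, against 0.469). The lowest and highest single-change values were 6.87e-12 and 0.474 for the cell cycle (ended by an estimated correlation and by fry), 6.74e-05 and 0.510 for chemokines, 5.79e-07 and 0.510 for alternative activation, 0.000161 and 0.510 for cholesterol synthesis (0.515 with an estimated correlation and the block), 9.19e-24 and 0.885 for maturing macrophages, 2.33e-05 and 0.640 for progenitors, 8.17e-08 and 0.581 for dendritic cells, 1.29e-19 and 0.581 for B cells and 9.25e-05 and 0.447 for eosinophils. Fry without the block called glucocorticoid receptor targets, interferon-stimulated genes and antigen presentation, and ended the other 4 calls of gene lists and all 5 of cell marker lists; at an adjusted p under 0.01 the calls of chemokines, alternative activation, maturing macrophages and progenitors ended. Some lists called neither without nor with the block were called otherwise: MAP kinase feedback without dexamethasone array 1, control array 2 or both arrays of experiment 1, antioxidant genes with the block without experiment 3, erythroid cells with every probe set, megakaryocytes without control array 1, and neutrophils and erythroid, T and NK and basophil cells without dexamethasone array 3. The block changed no call by camera other than those given with the results.

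The direction of 15 lists' tests turned in some alternative; the values are medians, which can keep their sign. With every probe set, antioxidant genes had -0.12, NF-kB genes -0.0683 and proteases -0.0175; without probe sets that can detect several transcripts, apoptosis regulators had -0.0743, NF-kB genes 0.0220, clock genes -0.20 and stromal cells 0.0556. With no filter, proteases had 0.0754 and T and NK cells 0.0427; with the lowest 60 percent left out, lipid handling had -0.0929, monocytes -0.48 and neutrophils -0.16. With quantile normalization, with and without the block, proteases had 0.0353; with the block the megakaryocyte list had -0.00361, and 0.0226 with quantile normalization too. On leaving out arrays the medians ran from -0.0223 to 0.35 for phagocytosis, -0.19 to 0.13 for apoptosis, -0.37 to 0.0692 for lipid handling, -0.16 to 0.0312 for NF-kB, -0.0937 to 0.15 for pattern recognition, -0.0948 to 0.35 for proteases, -0.20 to 0.23 for the clock, -0.53 to 0.10 for MAP kinase feedback, -0.52 to -0.29 for monocytes, -0.39 to 0.13 for neutrophils, -0.38 to 0.33 for megakaryocytes and -0.91 to 0.40 for basophils. The values of genes that turned ran from -0.27 to 0.11 for Nr3c1 (0.0729 with the mean over probe sets), -0.81 to 0.29 for Adgre1, -0.00236 to 0.63 for Il10, -2.32 to 0.0917 for Ms4a1, -1.44 to 0.14 for Gas6, -1.29 to 0.0321 for Cd3d, -1.57 to 0.15 for Ppbp and -2.05 to 0.50 for Mcpt8. The cause was not tested for any of these. Low signals near the pseudocount of 4.1 limit the precision of the lowest genes.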

Other observations

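The genes of this part were chosen after their values were seen, and so was its test. Those of the first paragraph stand for no group, since no list of such genes was fixed or tested. Orm1, which encodes orosomucoid, rose by 2.75 (SE 0.27, adjusted p = 0.00618), and the haptoglobin gene Hp rose by 1.84 (SE 0.12) in the paired fit, from 10.59 ± 0.64 to 12.43 ± 0.58 (n = 3). Crispld2, which encodes a secreted protein, rose by 2.92 in the paired fit. The enzyme genes Sult1a1, Aox3, Cbr2 and Hsd17b2 rose in the paired fit, by 3.70, 2.79, 2.74 and 2.61; the control levels of Aox3 (2.45) and Hsd17b2 (2.48) were close to the pseudocount, which sets the size of such differences. Genes lower in the paired fit and outside the lists included Acod1, which makes itaconate, by -2.82 (SE 0.45, to a level close to the pseudocount) and the kynurenine pathway gene Kmo by -1.60 (SE 0.19). Lower in it were also Spib (-3.16), Ly6d (-2.62), Cd72 (-2.30), Dntt (-2.06), Jchain (-1.83) and Bank1 (-1.40). The differences of Spib, Ly6d, Cd72 and Dntt were -5.09, -3.83, -3.73 and -3.14 in experiment 3. In experiments 1 and 2 they lay between -2.57 and -1.07. Jchain also had its largest fall in experiment 3 (-2.29), and Bank1 in experiment 2 (-1.53). Whether these falls came from monocytes or from fewer B cells or dendritic cells was not tested.

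Of 11 tested genes of the Ms4a family, which encode membrane proteins with 4 spans on neighbouring loci, 6 rose in the paired fit and 0 fell: Ms4a8a (4.07), Ms4a4b (2.06), Ms4a6d (1.35), Ms4a6c (1.18), Ms4a6b (1.11) and Ms4a4c (0.90). Among the other 12546 tested genes 365 rose (2.91%). A shared response of the family is a hypothesis; Fisher's exact test gave p = 2.6e-07 (two-sided), but the family was noticed in the same data, its genes are not independent, and probe sets of such similar genes may detect each other's transcripts, which was not tested. Ms4a1, a B cell gene of the family, differed by -1.23 and was not called.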
